A study of Homo sapiens with 14 samples.

How the data were processed

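RNA of 14 samples of sorted bone marrow cells was measured on Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with a column kit, and biotin-labelled target was made with a 2-cycle labelling kit. The submitters' processing notes name Affymetrix Expression Console and RMA, whose versions are not given in the sources used here. The deposited data hold a single log2 expression value per probe set and array, for 54675 probe sets from 1.63 to 14.8, a range that RMA log2 values take. Per the series design, the authors sorted the cells by flow cytometry and compared lesional with lymphoid cells by SAM, whose settings are not given in the sources used here. The description field of every sample speaks of lymphoid cells, so groups were taken from the title, source and cell type fields, which match one another in every sample.

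The deposited columns were not all normalized together. The median deposited log2 value of 1 of the 6 lymphoid arrays was 3.67, against 4.89 to 5.09 in the other 13 arrays. Between this array and any other, 0 to 2 probe sets had exactly the same value, against 157 to 584 per pair among the other 13. Its probe sets lay at a median of -0.93 from the median of the other 13 arrays. The plan made before the data were examined had the values as deposited as the main setting and quantile normalization of all arrays as an alternative. After these medians and ties were seen, and before any test was run, the settings were exchanged, so that quantile normalization of all 14 arrays is the main setting and the values as deposited are an alternative. The median change of all genes was 0.11 for lesional, 0.03 for blastic and 0.19 for myeloid against lymphoid cells and -0.06 for blastic against myeloid cells. On the values as deposited these medians were 0.29, 0.28, 0.28 and 0.11, and with each array centred on its median they were 0.07, 0.10, 0.01 and 0.19.

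Probe sets were named from the platform annotation. Of the 54675 probe sets, 62 were controls, 41097 had 1 gene symbol, 1801 had several and were left unnamed, and 11777 were not listed with a gene. Of those with 1 symbol, 41043 were matched by Entrez ID to a RefSeq gene table of assembly GRCh38.p14, used for current symbols only, and 54 kept the platform symbol. The platform annotation names no genome build, so no coordinates are given. Each gene was represented by its probe set with the highest mean over all arrays, which gave 19732 genes, and 11110 genes above log2 6 in at least 3 arrays were tested. For an array, the number of samples limits the precision. Where a named gene had several probe sets, they disagreed in sign for CD74 and PKM in myeloid against lymphoid cells and for CFLAR, GATA2 and TFRC in blastic against myeloid cells, and no gene was called both ways.

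Lesional samples (3 blastic, 3 myeloid and 1 erythroid) were compared with the 6 lymphoid samples of patients in a 2-group fit, and the other comparisons used a fit of all groups with 1 shared estimate of spread. Tests were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table, at a Benjamini-Hochberg adjusted p of 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Before the data were examined, 28 gene lists were fixed: T cell, NK and cytotoxic, B cell, plasma cell, stem and progenitor, HOX and MEIS, primary granule, secondary granule, mature neutrophil, monocyte, erythroid lineage, megakaryocyte and platelet, plasmacytoid dendritic, mast cell, basophil and eosinophil, marrow stroma, cell cycle, heme biosynthesis, ribosomal protein, recurrently mutated in MDS, DNA methylation and Polycomb, tumor suppressors methylated in MDS, interferon response, apoptosis regulators, MHC class II, Toll-like receptor and inflammasome, immediate early and stress, oxidative phosphorylation, and glycolysis. GATA2 is in 3 of these lists, and GZMB and ASXL1 are each in 2. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and comparisons. The single erythroid and healthy samples were set against the mean, SD and range of the 6 lymphoid samples without a test. The medians of their lists were ranked among 10000 random lists of the same size matched on mean expression in 20 bins.

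The genes named were chosen by a rule fixed in advance. In each tested comparison they are the 10 with the largest rise and the 10 with the largest fall among genes that passed limma and whose samples did not overlap between the groups, and up to 4 members of each list. For the erythroid sample they are the 10 largest differences each way outside the range of the lymphoid samples and above log2 8 in the higher one, and for the healthy sample the 5 largest each way. Of the 5 genes with the largest rise in the healthy sample, 1 was left out because its signal is known to vary with a common inherited difference. Sex-linked marker genes, antigen receptor segments and genes with common whole-gene deletions were not named. Members of lists outside this rule are named where 5 or fewer members rose or fell or where a single member was the exception, and those were chosen after their values were seen.

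Some patients gave more than 1 fraction, per the labels' patient numbers. Deviations from the group means correlated at 0.331 and 0.324 for the pairs of blastic and lymphoid samples and at 0.183 for the pair of blastic and myeloid samples of 1 patient, against -0.391 to 0.465 (median 0.004) for 42 pairs of other patients. The patient was therefore also used as a block, as a random effect (duplicateCorrelation consensus of 0.478 in the 2-group fit and 0.471 in the other) and as a fixed term.

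The tests were checked on simulated data of 11110 genes with independent noise. In each comparison 67 genes were changed by log2 1, 67 by log2 2 and 66 by log2 4. That is far fewer than were called against lymphoid cells in the real data, where the shares recovered may differ. For lesional against lymphoid cells limma recovered 9% of genes changed by log2 1, 79.1% by log2 2 and 98.5% by log2 4. The shares were 1.5%, 56.7% and 100% for blastic against lymphoid, 1.5%, 67.2% and 98.5% for myeloid against lymphoid and 3%, 44.8% and 95.5% for blastic against myeloid cells, and 3.7% to 6.7% of calls were false. Other settings chosen in advance were no filter and a filter at log2 7, the mean of probe sets, probe sets tested singly, other scalings, an intensity trend, array weights, the patient as a block, a SAM-type test with at most 100 permutations, the healthy sample added, the erythroid sample left out, other groupings of the fit and each sample left out in turn. After the data were seen, 5 were added: leaving out the array normalized apart on the values as deposited, leaving out the 2 lymphoid samples that carry myeloid transcripts, the GAPDH difference between 3' and 5' probe sets as a covariate, the patient as a fixed block for the 2 comparisons of myeloid cells, and the list tests with each array centred on its median. The 2 lymphoid samples were the one with the highest primary granule list mean (8.84 against 4.51 to 5.42 in the others) and the one with the highest mature neutrophil list mean (8.61 against 5.16 to 6.65).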

Results

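Gene expression was measured in bone marrow cells of patients with myelodysplastic syndrome (MDS), a clonal disorder in which blood-forming cells mature poorly. The cells had been separated by flow cytometry, and RNA from each fraction was hybridised to 1 of 14 Affymetrix Human Genome U133 Plus 2.0 arrays. Lymphoid cells came from 6 patients, blastic cells from 3, myeloid cells from 3 and erythroid cells from 1, with lymphoid cells of 1 healthy donor added. Among these patients, 2 gave both blastic and lymphoid cells and 1 gave both blastic and myeloid cells. The blastic, myeloid and erythroid samples made up the 7 lesional samples, and the lymphoid fractions are labelled as normal cells. No blastic, myeloid or erythroid cells of healthy donors were measured. Differences between lesional and lymphoid cells may therefore reflect lineage, MDS or both. Of 19732 genes on the arrays, 11110 lay above log2 6 in at least 3 arrays and were tested. The first principal component held 35.8% of the variance and separated all 7 lymphoid arrays (scores of -77.1 to -44.1) from all 7 lesional arrays (41.6 to 76.5). Levels below are log2 values with their SD across samples, and the number of arrays limits the precision. The files hold no detection calls, so a fold change with 1 level below log2 6 may rest on background. It is then only a lower bound, and the order of such genes is uncertain.

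Lesional cells were first compared with the lymphoid cells of the patients, the contrast named in the series design. Genes of T cells and natural killer (NK) cells were the lowest in lesional cells. RORA, a nuclear receptor of T cells and innate lymphocytes, lay at 10.98 ± 0.73 in lymphoid cells (n = 6) and at 3.47 ± 0.80 in lesional cells (n = 7), which was at least 183-fold lower. IL7R, the interleukin 7 receptor that lymphocytes need to survive, fell from 11.32 ± 0.86 to 4.15 ± 0.23, or at least 144-fold lower. Among the genes that rose most were MS4A3 and CXCL8. MS4A3, a membrane protein of granulocyte and monocyte progenitors, rose from 4.68 ± 1.67 to 10.87 ± 2.21, or at least 73.4-fold higher. CXCL8, a chemokine that attracts neutrophils, rose from 7.93 ± 1.97 to 13.42 ± 1.09, or 44.8-fold higher. In the healthy lymphoid sample CXCL8 lay at 11.65, above the 11.22 of the erythroid sample.

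In limma, the log2 change was -7.52 for RORA (SE 0.408, adjusted p = 1.83e-08), -7.17 for IL7R (SE 0.339, adjusted p = 4.37e-09), 6.20 for MS4A3 (SE 0.963, adjusted p = 0.000544) and 5.49 for CXCL8 (SE 0.763, adjusted p = 0.000232). The other genes with the largest rise were PTX3, a secreted pattern recognition protein (63.8-fold higher), the eosinophil ribonuclease RNASE2 (50.9-fold), the small GTPase RAB13 (41.5-fold) and the mast cell carboxypeptidase CPA3 (39.7-fold). They also included the glycosyltransferase B3GNT5 (31-fold), the progenitor transcription factor MYB (25.5-fold), the ribonucleotide reductase subunit RRM2 (23.9-fold) and the folate hydrolase GGH (21.5-fold). The other genes with the largest fall were the granzymes GZMA (154-fold lower), GZMK (119-fold) and GZMH (93.7-fold). Among them were also FGFBP2, a secreted product of cytotoxic lymphocytes (138-fold), the cytolytic protein GNLY (102-fold), the NK receptor KLRB1 (93.2-fold), the T cell transcription factor BCL11B (92.4-fold) and the T cell coreceptor CD8A (89.5-fold). Both rankings cover only genes that passed limma and whose samples did not overlap between the groups.

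Gene lists fixed in advance were tested with camera, which compares the genes of a list with all other genes, and 13 of 28 lists passed in this comparison. Of 26 T cell genes measured, 25 fell (25 adjusted over the list alone), CD4 being the exception, with a median log2 change of -5.01 and a camera adjusted p of 1.3e-40. Of 22 NK and cytotoxic genes, 18 fell (20 adjusted over the list alone; median -5.10, camera adjusted p = 4.32e-25). Both lists kept the call with an estimated correlation, at adjusted p = 2.83e-05 for the T cell list and 0.00246 for the NK list. Of 17 B cell genes, 8 fell (12 adjusted over the list alone; median -1.31, camera adjusted p = 9.84e-08), among them the coactivator POU2AF1 (34.2-fold lower), the surface protein MS4A1 (32.2-fold) and the B cell regulator PAX5 (22-fold). The B cell call was lost at adjusted p = 0.242 with an estimated correlation. Of 23 interferon response genes, 5 fell (5 adjusted over the list alone; median -0.81, camera adjusted p = 0.00051), including IFIT2 (11-fold lower) and OASL (5.37-fold). The interferon call was lost at adjusted p = 0.402 with an estimated correlation.

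Cell division genes rose together in lesional cells: 24 of 26 measured (25 adjusted over the list alone) with a median of 2.73 and a camera adjusted p of 1.73e-16, led by RRM2, the thymidylate synthase TYMS (21.1-fold higher), the cyclin CCNB2 (16.1-fold) and the spindle protein NUSAP1 (13.7-fold). With an estimated correlation the adjusted p = 0.192. Of 9 genes of the primary granules of granulocyte precursors, 8 rose (9 adjusted over the list alone), DEFA4 being the exception, with a median of 4.70 and a camera adjusted p of 6.87e-06 (adjusted p = 0.275 with an estimated correlation). The peroxidase MPO was 48.4-fold higher and the elastase ELANE 43.5-fold higher, at log2 5.60 and 5.44, and at 6.84 and 6.57 without 1 lymphoid sample. Of 15 stem and progenitor genes, 4 rose (7 adjusted over the list alone), namely MYB, the transcriptional cofactor LMO2 (17.7-fold higher), the secreted protein CYTL1 (15.2-fold) and the transcription factor GATA2 (6.4-fold). Their median was 1.88 (camera adjusted p = 0.000237, and adjusted p = 0.415 with an estimated correlation). Of 6 mast cell, basophil and eosinophil genes, 4 rose (6 adjusted over the list alone; median 3.04, camera adjusted p = 0.0025, and adjusted p = 0.294 with an estimated correlation), with CLC 13.6-fold higher and PRG2 10.1-fold higher beside CPA3 and GATA2. When each of the 13 samples was left out in turn, the call was lost in 9 fits for GATA2 and in 3 for PRG2. In 1 of the 6 lymphoid samples the mean of the primary granule list was 8.84, against 4.51 to 5.42 in the other 5, and that of the stem and progenitor list was 6.75, against 5.07 to 5.39.

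The other lists that passed camera held secondary granule, monocyte, heme and metabolic genes. No secondary granule gene passed the test (0 of 13 in limma, and 0 adjusted over the list alone), although the median was 3.23 and the camera adjusted p was 0.00661 (adjusted p = 0.635 with an estimated correlation). That call was also lost with the patient as a random block (camera adjusted p = 0.0595) and with the GAPDH covariate (0.163), in a range of 0.00115 to 0.163 over 22 other settings. Of 13 monocyte genes, 4 rose (4 adjusted over the list alone; median 2.06, camera adjusted p = 0.00749, and adjusted p = 0.483 with an estimated correlation), led by the carboxypeptidase CPVL (9.36-fold higher). The monocyte call was lost with the mean of probe sets (camera adjusted p = 0.0505, in a range of 0.000659 to 0.0505 over the other settings). Of 10 heme biosynthesis genes, 4 rose (7 adjusted over the list alone; median 1.53, camera adjusted p = 0.0182, and adjusted p = 0.524 with an estimated correlation), led by ALAS1, the first enzyme of the pathway outside red cells (6.94-fold higher). The heme call was also lost with the mean of probe sets (camera adjusted p = 0.0639, in a range of 0.00403 to 0.0639). Of 28 oxidative phosphorylation genes, 8 rose (11 adjusted over the list alone; median 0.72, camera adjusted p = 0.000338, and adjusted p = 0.474 with an estimated correlation), led by UQCRC1 (4.58-fold higher). Of 19 glycolysis genes, 5 rose (6 adjusted over the list alone; median 0.76, camera adjusted p = 0.0149, and adjusted p = 0.286 with an estimated correlation), led by the enolase ENO1 (3.22-fold higher). A control for RNA quality, the difference between the 3' and 5' probe sets of GAPDH, was smaller in lesional arrays, at 1.604 ± 0.592 against 2.452 ± 0.759 in lymphoid arrays (exact two-sided permutation test, p = 0.0466), while that of ACTB was 3.27 ± 0.78 against 3.91 ± 0.69 (exact two-sided permutation test, p = 0.146). These tests take the arrays as independent, although 3 patients gave 2 arrays each. In the 2 patients with both kinds the GAPDH difference went opposite ways.

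The remaining 15 lists did not pass camera in this comparison. Ribosomal protein genes, none of 40 of which passed limma, had a median of -0.04 (camera adjusted p = 0.305). The erythroid lineage list had a median of 1.15 (camera adjusted p = 0.0644, with CA2, ERMAP and TMOD1 rising). The medians were 1.90 for the mature neutrophil list (0.144, with CSF3R and TREM1 rising), 0.70 for the HOX and MEIS list (0.372) and 0.29 for the megakaryocyte and platelet list (0.321, with only the matrix protein SPARC rising). The Toll-like receptor and inflammasome list had a median of 0.34 (camera adjusted p = 0.151), with TLR2, IRAK3, PYCARD and the cytokines IL1B and IL18 rising and LY96 falling. The MHC class II list had a median of -0.40 (0.308), with only HLA-DOB, a B cell modulator of peptide loading, falling. Genes recurrently mutated in MDS had a median of 0.10 (camera adjusted p = 0.733), with 5 rising (IDH1, IDH2, DDX41, CEBPA and GATA2) and ASXL1 falling. The DNA methylation and Polycomb list had a median of -0.28 (0.554), with UHRF1, DNMT3B and CBX2 rising and CBX7 and ASXL1 falling. The tumor suppressors methylated in MDS had a median of 0.25 (0.528), with CTNNA1 and DAPK1 rising and SOCS1 falling. The apoptosis list had a median of -0.12 (camera adjusted p = 0.361, with BAX and BID rising and FASLG and TNFSF10 falling). The immediate early and stress list had a median of -0.12 (0.556, with EGR1, ATF3 and IER3 rising and JUNB and DNAJB1 falling) and the plasma cell list -0.07 (0.411, with JCHAIN and IRF4 falling). The plasmacytoid dendritic list had a median of 0.06 (camera adjusted p = 0.464) with only GZMB falling, a granzyme shared with cytotoxic lymphocytes. The marrow stroma list had a median of 0.16 (camera adjusted p = 0.463) with only the adhesion molecule VCAM1 falling. In these last lists the median was above 0 while the mean and the test were below it. When each of the 13 samples was left out in turn, several single-gene calls above were lost. TNFSF10 was lost in 12 fits, EGR1 in 10, CSF3R, GATA2 and TMOD1 in 9, IDH1 in 8, LY96 in 7, JUNB in 6, CA2 in 4, IRF4 in 3 and PYCARD in 1. Among genes counted above without a name, FECH was lost in 9, MX1, CD36, CLEC7A and NDUFB5 in 8 and IFIT3 in 6. They belong to the heme (FECH), interferon (MX1, IFIT3), monocyte (CD36, CLEC7A) and oxidative phosphorylation (NDUFB5) lists.

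In total, 2183 of the 11110 genes passed limma at an adjusted p of 0.05, 1223 higher and 960 lower in lesional cells (56% higher), and 1993 of them changed at least 2-fold. The 2 groups did not overlap in 842 genes, 7.6% of those tested against the 0.117% that chance gives, and 827 of these also passed limma. The median change of all genes was 0.11, and 0.29 on the values as deposited, on which the split was 1171 higher and 584 lower (66.7% higher). With the patient as a fixed block, which leaves 2 residual degrees of freedom, 47 genes passed limma, 2 higher and 45 lower, and 1826 had an unadjusted p under 0.05. With that block the contrast rests on the 2 patients with both blastic and lymphoid cells. It thus holds no difference of myeloid or erythroid cells. Array weights gave 3525 genes, a SAM-type test 3365 and the GAPDH covariate 1408. Of 87 genes chosen by the naming rule that passed limma, 72 passed whichever sample was left out.

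**Figure D1:**
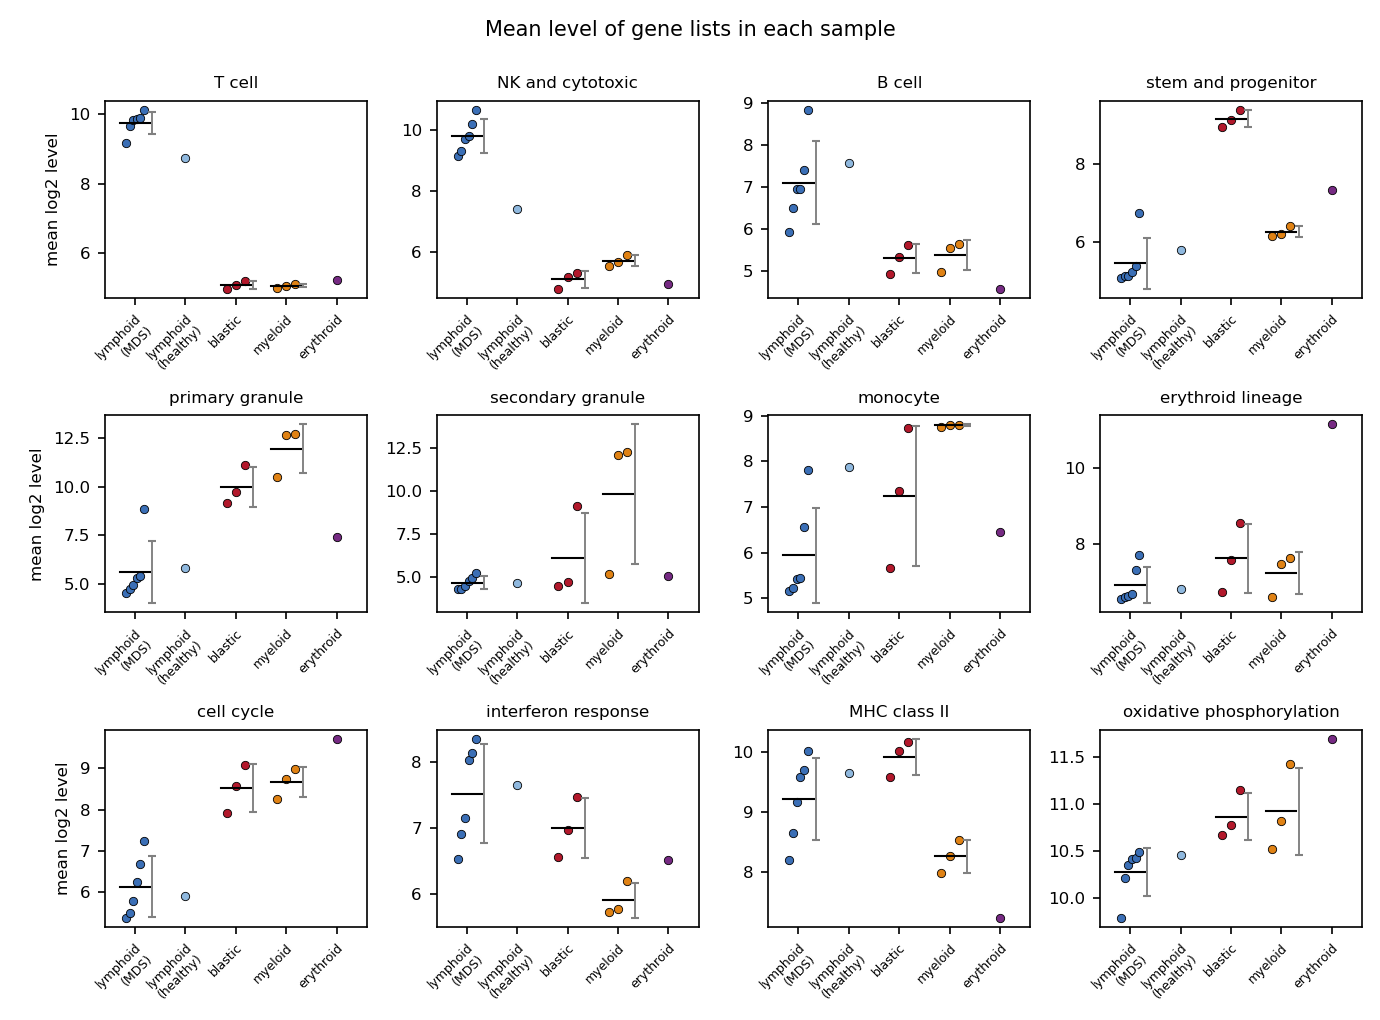
Mean log2 level of 12 gene lists (y axis) in each sample, by group (x axis). Each dot is a sample, black lines are group means and grey bars are SDs, and single samples have neither. The T cell list lay at 9.76 ± 0.32 in the patients' lymphoid samples and at 5.09 ± 0.11 and 5.07 ± 0.05 in blastic and myeloid samples.

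Blastic cells, the immature fraction, were compared with the lymphoid cells of the patients. The genes that rose most included markers of stem and progenitor cells and of early mast cells and basophils. DLK1, a Notch ligand homologue made by immature cells, rose from 5.40 ± 2.47 (n = 6) to 12.39 ± 0.56 (n = 3), or at least 127-fold higher. CPA3 rose from 4.37 ± 1.16 to 11.10 ± 1.39, or at least 107-fold higher. KIT, the receptor for stem cell factor, rose at least 39.7-fold from 5.73 ± 1.15 to 11.04 ± 1.34. GZMA, a protease of killer lymphocytes, fell from 11.64 ± 1.17 to 3.82 ± 0.18, or at least 226-fold lower.

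By limma, the log2 change was 6.99 for DLK1 (SE 1.20, adjusted p = 0.0028), 6.74 for CPA3 (SE 0.804, adjusted p = 0.000219) and -7.82 for GZMA (SE 0.654, adjusted p = 9.77e-06). Further genes with the largest rise were the methionine sulfoxide reductase MSRB3 (129-fold higher), the coagulation inhibitor TFPI (110-fold), NREP (80.4-fold), CYTL1 (65.9-fold), PTX3 (54.7-fold), the glutathione transferase MGST1 (51.3-fold) and the chemokines CXCL2 (48.3-fold) and CXCL8 (46.7-fold). The log2 change of MSRB3 ranged from 0.35 to 7.01 over its 4 probe sets. CXCL2 lay at 9.49 in blastic cells, 3.89 in the patients' lymphoid cells and 7.74 in the healthy lymphoid sample. Further genes with the largest fall were RORA (174-fold lower), FGFBP2 (145-fold), GZMH (139-fold), IL7R (134-fold), GZMK (126-fold), GNLY (116-fold), BCL11B (109-fold), the TGF-beta coreceptor TGFBR3 (105-fold) and CD8A (102-fold). Genes that did not pass limma or whose samples overlapped between the groups were left out of both rankings.

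Of 15 stem and progenitor genes, 11 rose in blastic cells (14 adjusted over the list alone; median 4.04, camera adjusted p = 2.29e-13), among them CYTL1, KIT, MYB (38.7-fold higher) and GATA2 (26.4-fold). This call held at adjusted p = 0.0114 with an estimated correlation. The list mean was 9.17 ± 0.22 in blastic (n = 3), 6.25 ± 0.14 in myeloid (n = 3) and 5.44 ± 0.65 in lymphoid samples (n = 6). Of 26 T cell genes, 24 fell (26 adjusted over the list alone; median -5.04, camera adjusted p = 4.52e-42). Of 22 NK and cytotoxic genes, 18 fell (20 adjusted over the list alone; median -5.25, camera adjusted p = 2.36e-27). Both held with an estimated correlation, at adjusted p = 0.000122 and 0.00246. Of 9 primary granule genes, 7 rose (8 adjusted over the list alone; median 4.80, camera adjusted p = 2.69e-06, and adjusted p = 0.242 with an estimated correlation), led by MPO (99.9-fold higher, lost in 2 of 9 leave-one-out fits). The log2 change of MPO was 6.64, and 7.89 without the lymphoid sample with the highest primary granule list mean. Of 6 mast cell, basophil and eosinophil genes, 4 rose (6 adjusted over the list alone; median 4.40, camera adjusted p = 2.27e-06, and adjusted p = 0.139 with an estimated correlation), with the IgE receptor chain FCER1A 30.8-fold higher and the tryptase TPSAB1 4.77-fold higher (lost in 1 of 9). Of 26 cell cycle genes, 20 rose (24 adjusted over the list alone; median 2.35, camera adjusted p = 3.46e-15, and adjusted p = 0.198 with an estimated correlation).

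Smaller list changes in blastic cells all lost their call with an estimated correlation. Of 17 B cell genes, 6 fell (6 adjusted over the list alone; median -1.34, camera adjusted p = 1.62e-06, and adjusted p = 0.294 with an estimated correlation). The heme biosynthesis list rose with 3 of 10 genes, UROD, FECH and UROS (5 adjusted over the list alone; median 1.16, camera adjusted p = 0.00662, and adjusted p = 0.39 with an estimated correlation). The oxidative phosphorylation list rose with 2 of 28 genes, UQCRC1 and ATP5MC1 (1 adjusted over the list alone; median 0.55, camera adjusted p = 0.0089, and adjusted p = 0.524 with an estimated correlation). In the glycolysis list only ENO1 of 19 genes rose (3 adjusted over the list alone; median 0.49, camera adjusted p = 0.0223, and adjusted p = 0.268 with an estimated correlation). In the monocyte list only MS4A6A of 13 genes rose (1 adjusted over the list alone; median 1.41, camera adjusted p = 0.0296, and adjusted p = 0.596 with an estimated correlation). The monocyte call was lost in 8 of the 22 other settings, with camera adjusted p from 0.000689 to 0.346, the highest without 1 of the blastic samples, and also on the values as deposited (0.093), with the mean of probe sets (0.076) and without any of 4 of the lymphoid samples (0.0505, 0.0568, 0.0675 and 0.0681). The heme call was lost without 1 of the blastic samples (camera adjusted p = 0.0877, in a range of 0.000592 to 0.0877), as was the oxidative phosphorylation call (0.103, in a range of 0.00076 to 0.103). The glycolysis call was lost without another of them (camera adjusted p = 0.0556, in a range of 0.00174 to 0.0556) and with the mean of probe sets (0.0505). The plasma cell, plasmacytoid dendritic, DNA methylation and Polycomb, and immediate early lists had a median and a mean of opposite sign, and none of the 4 passed camera. When each of the 9 samples was left out in turn, the limma call was lost in 6 fits for FECH and ATP5MC1, in 3 for UROS and MS4A6A and in 2 for UROD.

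Altogether 1176 genes passed limma, 730 higher and 446 lower in blastic cells (62.1% higher). On the values as deposited 833 passed, 600 higher and 233 lower (72% higher). The groups did not overlap in 1822 genes, 16.4% of those tested against the 2.381% that chance gives, and 1057 of these passed limma. With the patient as a random block 1959 genes passed, and 1175 of the 1176 were among them. With the patient as a fixed block, which leaves 1 residual degree of freedom, limma called 0 genes, with 1918 at an unadjusted p of 0.05, while a SAM-type test without the block called 1703. Array weights gave 2262. Leaving out 1 of the 3 blastic samples gave 588 genes and leaving out another gave 701. Of 77 genes chosen by the naming rule that passed limma, 49 passed whichever sample was left out.

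Myeloid cells were compared with the same lymphoid samples. Genes of granulocyte precursors were among those that rose most. MS4A3 rose from 4.68 ± 1.67 (n = 6) to 12.87 ± 0.19 (n = 3), or at least 294-fold higher. CTSG, the granule protease cathepsin G, rose from 6.35 ± 0.70 to 13.87 ± 0.28, or 184-fold higher. CD69, an early activation marker of lymphocytes, fell from 12.58 ± 0.54 to 6.12 ± 2.95, or at least 87.9-fold lower, with 2 of the 3 myeloid levels of CD69 below log2 6.

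The limma log2 change was 8.20 for MS4A3 (SE 0.882, adjusted p = 7.62e-05), 7.53 for CTSG (SE 0.766, adjusted p = 4.46e-05) and -6.46 for CD69 (SE 0.882, adjusted p = 0.000429, and -5.32 to -8.12 with 1 sample left out). PTX3 (167-fold higher), RNASE2 (160-fold), the growth factor EREG (135-fold), the protease inhibitor CSTA (108-fold), PCOLCE2 (74.9-fold), CXCL8 (71.3-fold), the granule protein AZU1 (61.1-fold) and RAB13 (59.3-fold) completed the largest rises. RORA (189-fold lower), IL7R (157-fold), FGFBP2 (121-fold), GZMK (107-fold), KLRB1 (101-fold), GZMA (98.8-fold), GNLY (96.5-fold), the lymphocyte GTPase GIMAP7 (83.4-fold) and the T cell kinase LCK (82.9-fold) completed the largest falls. Rises and falls were ranked only among genes that passed limma and whose samples did not overlap between the groups.

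All 9 primary granule genes measured rose in myeloid cells (9 adjusted over the list alone; median 6.12, camera adjusted p = 1.23e-07), with ELANE 151-fold higher, and the call was lost at adjusted p = 0.192 with an estimated correlation. Of 13 secondary granule genes, 12 rose (13 adjusted over the list alone; median 5.36, camera adjusted p = 4.02e-06, and adjusted p = 0.439 with an estimated correlation), among them the adhesion molecule CEACAM8 (116-fold higher), CRISP3 (76.2-fold) and lactoferrin, LTF (55.6-fold). Of 9 leave-one-out fits, 6 lost the call of LTF and 2 those of CEACAM8 and CRISP3. Over these fits the log2 change ranged from 5.38 to 9.80 for CEACAM8 and from 4.85 to 8.99 for CRISP3. The mean of the secondary granule list was 9.82 ± 4.05 across the 3 myeloid samples, from 5.14 to 12.25. The lowest of them lay within the range of the patients' lymphoid samples (4.26 to 5.23), so the rise was not seen in every myeloid sample. Of 13 mature neutrophil genes, 6 rose (7 adjusted over the list alone; median 2.71, camera adjusted p = 0.00204, and adjusted p = 0.483 with an estimated correlation). The lowest myeloid mean of that list, 7.18, was below the highest lymphoid one, 8.61. Of 13 monocyte genes, 7 rose (9 adjusted over the list alone; median 2.82, camera adjusted p = 0.000161, and adjusted p = 0.39 with an estimated correlation). The calcium-binding protein S100A12 was 66.4-fold higher, the nuclear protein MNDA 50.6-fold, the lectin FCN1 56.1-fold and the oxidase subunit CYBB 23-fold, with S100A12 and FCN1 each lost in 2 of the 9 fits. Of 15 Toll-like receptor and inflammasome genes, 6 rose (6 adjusted over the list alone; median 0.90, camera adjusted p = 0.00424, and adjusted p = 0.192 with an estimated correlation), including IRAK3 (24.8-fold higher) and the cytokine IL18 (23.2-fold). Of 26 cell cycle genes, 19 rose (23 adjusted over the list alone; median 2.60, camera adjusted p = 3.4e-12, and adjusted p = 0.263 with an estimated correlation).

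Of 23 interferon response genes, 8 fell (8 adjusted over the list alone; median -1.61, camera adjusted p = 6.87e-06, and adjusted p = 0.268 with an estimated correlation), with IFIT2 17-fold, EPSTI1 10.6-fold, IFIT3 9.17-fold and IFIT1 8.52-fold lower. Of 9 leave-one-out fits, 6 lost the call of IFIT3, 5 that of IFIT1 and 1 that of IFIT2. Of 10 MHC class II genes, 3 fell (3 adjusted over the list alone; median -1.05, camera adjusted p = 0.00775, and adjusted p = 0.439 with an estimated correlation), namely HLA-DPB1 (4.16-fold lower), the invariant chain CD74 (3.25-fold) and HLA-DPA1 (2.76-fold), of which CD74 was lost in 6 and HLA-DPB1 in 5 of the 9. The probe sets of CD74 ranged from -1.70 to 0.29, and with the mean of probe sets the MHC class II call was lost (camera adjusted p = 0.0505, in a range of 0.000254 to 0.0505 over the 22 other settings). Of 26 T cell genes, 25 fell (25 adjusted over the list alone; median -4.86, camera adjusted p = 5.61e-33). Of 22 NK and cytotoxic genes, 18 fell (18 adjusted over the list alone; median -4.81, camera adjusted p = 1.07e-17). Both held with an estimated correlation, at adjusted p = 0.000237 and 0.0106. Of 17 B cell genes, 6 fell (6 fell and 1 rose adjusted over the list alone; median -1.10, camera adjusted p = 2.45e-05, and adjusted p = 0.39 with an estimated correlation). Of 19 glycolysis genes, 9 rose (11 adjusted over the list alone; median 0.96, camera adjusted p = 0.00412, and adjusted p = 0.192 with an estimated correlation), led by HK3, a hexokinase of myeloid cells (14.5-fold higher). Of 28 oxidative phosphorylation genes, 5 rose (5 adjusted over the list alone; median 0.67, camera adjusted p = 0.00662, and adjusted p = 0.522 with an estimated correlation). Without 1 of the myeloid samples this call was lost (camera adjusted p = 0.177, in a range of 0.000234 to 0.177). The plasmacytoid dendritic, marrow stroma, mutated, tumor suppressor and apoptosis lists had a median whose sign differed from that of the mean or the test, and none of the 5 passed camera.

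In total, 2013 genes passed limma, 1061 higher and 952 lower in myeloid cells (52.7% higher). On the values as deposited 1150 genes passed, 649 higher and 501 lower. The majority turned with each array centred on its median (660 higher and 883 lower, 42.8% higher) and on the values as deposited without the array normalized apart (643 and 772, 45.4% higher). With that array left out at the main normalization it stayed, at 880 higher and 864 lower. It also turned without either of 2 of the myeloid samples (604 higher and 625 lower, and 822 and 832). Non-overlapping groups were found for 2093 genes, 18.8% of those tested against the 2.381% that chance gives, and 1627 of these passed limma. Leaving out 1 of the 3 myeloid samples gave 1193 genes and leaving out another gave 1229. With the patient as a fixed block, added after the data were seen and leaving 1 residual degree of freedom, limma called 0 genes, with 1011 at an unadjusted p of 0.05, while a SAM-type test without the block called 2762. No patient gave both fractions, so the block compares them through blastic cells, and 66 of the 2013 genes changed sign with it. Array weights gave 4742 genes and the GAPDH covariate 1323. Of 89 genes chosen by the naming rule that passed limma, 58 passed whichever sample was left out.

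**Figure D2:**
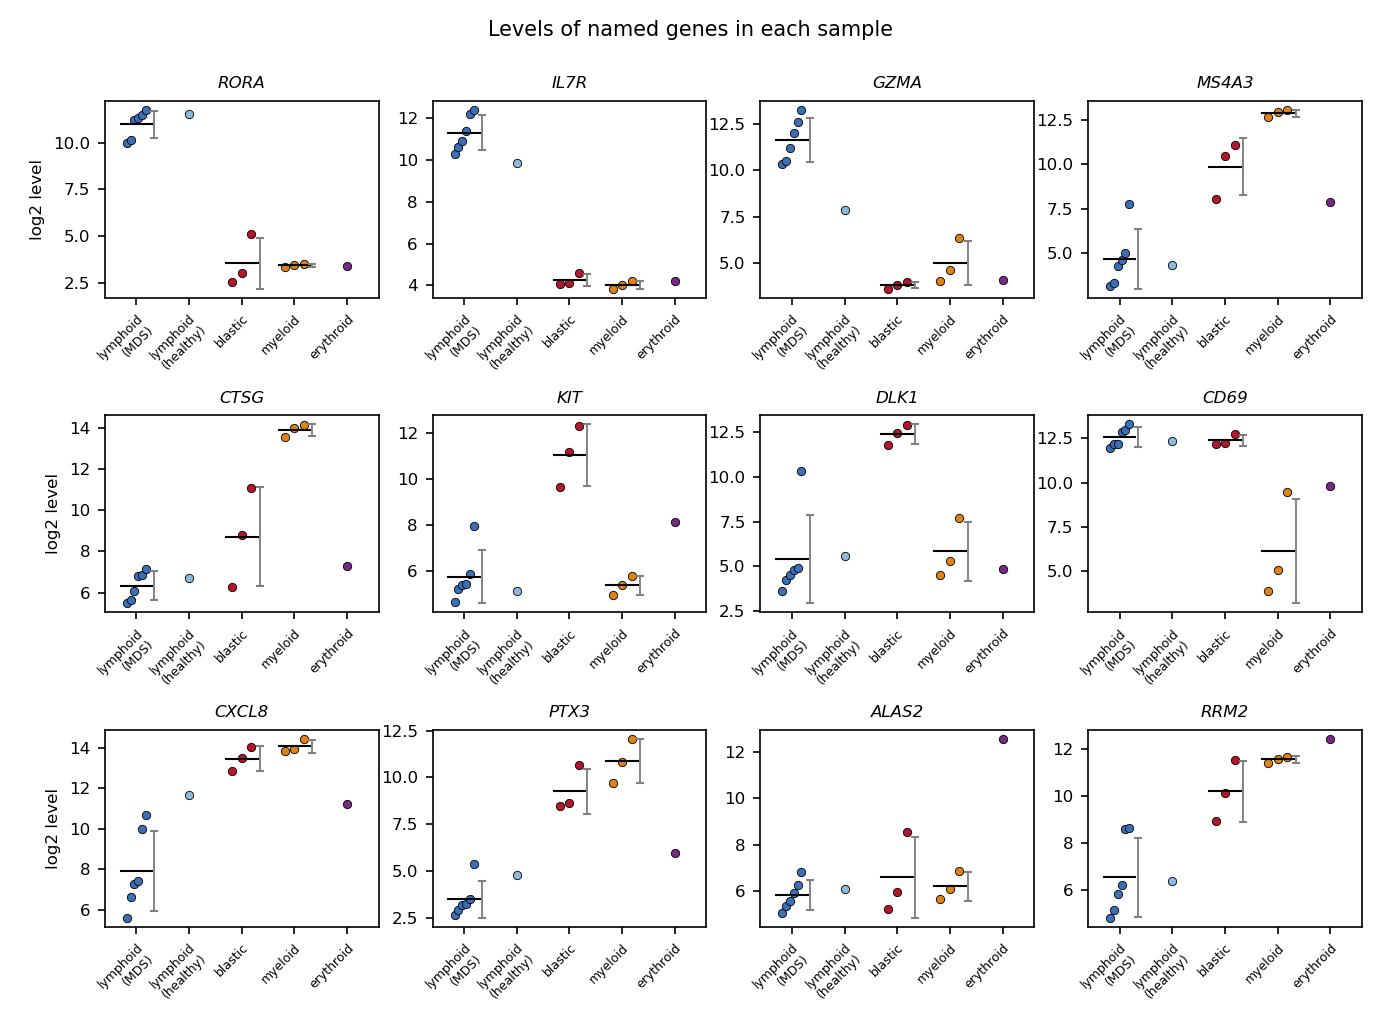
Log2 level of 12 named genes (y axis) in each sample, by group (x axis). Each dot is a sample, black lines are group means and grey bars are SDs, and single samples have neither. KIT lay at 11.04 ± 1.34 in blastic and at 5.35 ± 0.42 in myeloid samples, and CTSG at 8.72 ± 2.39 and 13.87 ± 0.28.

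Blastic and myeloid cells were then compared with each other, which also tests whether their changes against lymphoid cells differ. Genes of immature cells were among those higher in blastic cells, and genes of the neutrophil and monocyte lineages among those lower. KIT lay at 11.04 ± 1.34 in blastic (n = 3) and at 5.35 ± 0.42 in myeloid cells (n = 3), at least 51.5-fold higher. CD69 lay at 12.40 ± 0.31 and 6.12 ± 2.95, at least 77.8-fold higher in blastic cells, against 12.58 ± 0.54 in the lymphoid cells of the patients (n = 6). CTSG lay at 8.72 ± 2.39 and 13.87 ± 0.28, 35.6-fold lower.

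The limma log2 difference was 5.69 for KIT (SE 0.78, adjusted p = 0.00557), 6.28 for CD69 (SE 1.02, adjusted p = 0.0179, and 5.15 to 7.95 with 1 sample left out) and -5.16 for CTSG (SE 0.884, adjusted p = 0.0203). Higher in blastic cells were also ZBTB8A (48.6-fold), the G protein subunit GNAI1 (41.6-fold), TFPI (39.3-fold), the RNA-binding stem cell regulator MSI2 (30.2-fold), DNTT, the terminal transferase of early lymphocytes (29.1-fold), C1QTNF4 (28.5-fold), the actin-binding protein ABLIM1 (26.2-fold) and GATA2 (19.1-fold). Lower were LIN7A (29.5-fold), PCOLCE2 (26-fold), ALOX5AP, which serves leukotriene synthesis (19.3-fold), CYBB (19.3-fold) and NCF1 (11.7-fold), both of the NADPH oxidase, the lectin LGALS3 (19.2-fold), SERPINB10 (15.1-fold), HK3 (12.3-fold) and LRG1 (11.1-fold). Of these 20 genes, 9 passed however 1 sample of either group was left out, and 11 were lost at least once, among them CD69, CTSG, TFPI and DNTT, with C1QTNF4 lost in all 6. For GATA2 the probe sets ranged from -0.22 to 4.26, and for MSI2 from 0.37 to 4.92. MSI2 lay at 8.51 in the patients' lymphoid, 9.08 in blastic and 4.16 in myeloid samples, and ABLIM1 at 10.52, 8.87 and 4.16. Like CD69, both were thus low in myeloid cells rather than clearly raised in blastic cells. The other genes ranked as higher in blastic cells also lay above the patients' lymphoid mean there.

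The stem and progenitor list was higher in blastic cells, with 4 of 15 genes passing limma, KIT, GATA2, the natriuretic peptide receptor NPR3 (16.3-fold) and the kinase CDK6 (10.7-fold), and 10 adjusted over the list alone. Its median was 3.42 (camera adjusted p = 1.46e-13), and it was the only list here to hold with an estimated correlation, at adjusted p = 0.0114. The MHC class II list was higher with a median of 1.80 (camera adjusted p = 5.82e-07, and adjusted p = 0.192 with an estimated correlation), where only HLA-DPA1 of 10 genes passed (5.23-fold) and 6 adjusted over the list alone. The mast cell, basophil and eosinophil list was higher (median 2.19, camera adjusted p = 0.000143, and adjusted p = 0.198 with an estimated correlation), with GATA2 of 6 genes passing and 4 adjusted over the list alone. The interferon response list was higher (median 0.92, camera adjusted p = 0.000439, and adjusted p = 0.39 with an estimated correlation), with EPSTI1 of 23 genes passing (10.9-fold) and 2 adjusted over the list alone. The list of genes recurrently mutated in MDS was higher (median 0.40, camera adjusted p = 0.0202, and adjusted p = 0.286 with an estimated correlation), with GATA2 alone of 27 genes passing, also when adjusted over the list alone (1). Its call was lost with the stricter filter at log2 7 (camera adjusted p = 0.0754) and without 1 of the blastic samples (0.0683), in a range of 0.00108 to 0.0754 over the other settings. Of 6 leave-one-out fits, 4 lost the limma calls of CDK6 and EPSTI1 and 2 that of HLA-DPA1.

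Lower in blastic than in myeloid cells was the secondary granule list, with 0 of 13 genes passing limma and 0 adjusted over the list alone (median -3.74, camera adjusted p = 7.15e-07, and adjusted p = 0.421 with an estimated correlation). So was the mature neutrophil list, likewise with 0 of 13 and 0 adjusted over the list alone (median -1.83, camera adjusted p = 0.00117, and adjusted p = 0.474 with an estimated correlation). The primary granule list was lower with CTSG alone of 9 genes passing (1 adjusted over the list alone; median -1.86, camera adjusted p = 0.00765, and adjusted p = 0.474 with an estimated correlation). The sample means of these lists overlapped between the groups. Blastic against myeloid means were 4.47 to 9.11 against 5.14 to 12.25 for the secondary granule list. They were 6.24 to 8.89 against 7.18 to 10.53 for the mature neutrophil list, and 9.16 to 11.14 against 10.50 to 12.71 for the primary granule list. Those of the monocyte list did not overlap (5.67 to 8.73 against 8.76 to 8.80). The monocyte list was lower with CYBB alone of 13 genes passing (2 adjusted over the list alone; median -1.30, camera adjusted p = 0.00531, and adjusted p = 0.483 with an estimated correlation). The monocyte call was lost with the mean of probe sets (camera adjusted p = 0.0536) and without 1 of the blastic samples (0.163), in a range of 8.06e-05 to 0.163. The Toll-like receptor and inflammasome list was lower with 0 of 15 passing limma and 0 adjusted over the list alone (median -0.62, camera adjusted p = 0.0182, and adjusted p = 0.268 with an estimated correlation). Without 1 of the blastic samples its call was lost (camera adjusted p = 0.0725, in a range of 0.00124 to 0.0725). The T cell, plasma cell and plasmacytoid dendritic lists, none of which passed camera, had a median whose sign differed from that of the mean or the test.

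**Figure D3:**
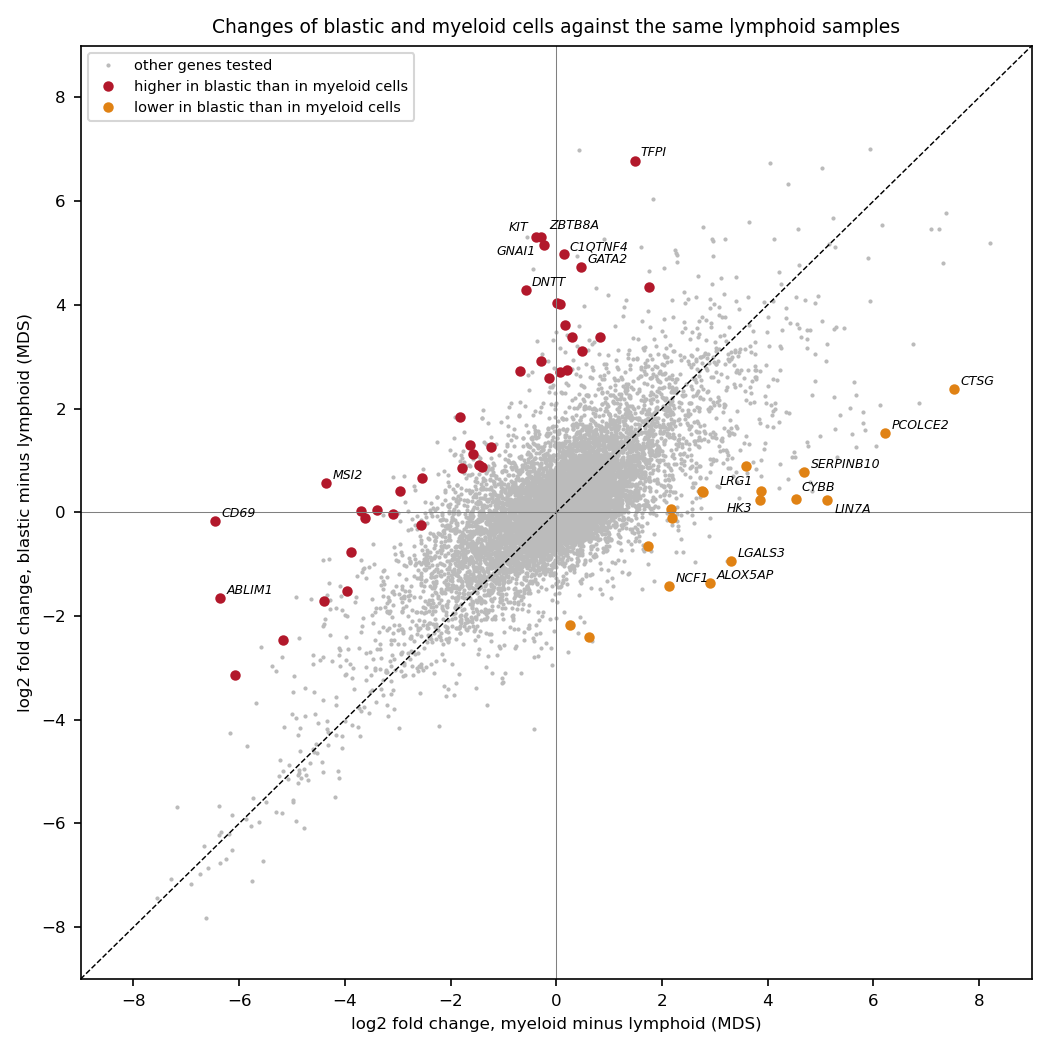
Log2 fold change against the lymphoid cells of the patients in myeloid cells (x axis) and blastic cells (y axis), 1 dot per gene tested. Red dots are the 41 genes higher and orange dots the 18 genes lower in blastic than in myeloid cells, the labelled ones are the 20 with the largest differences, and the dashed line marks equal change.

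Altogether 59 genes passed limma, 41 higher and 18 lower in blastic cells (69.5% higher), with a smallest adjusted p of 0.00389. All 59 were among the 2382 genes whose samples did not overlap between the groups, 21.4% of those tested against the 10% that chance gives. On the values as deposited 22 passed, 13 higher and 9 lower (59.1% higher), and with the patient as a random block 141 passed. A fit of the 2 groups alone called 0 in limma, with 1312 at an unadjusted p of 0.05. So did the patient as a fixed block, added after the data were seen, with 838 unadjusted and 1 residual degree of freedom. A SAM-type test gave 16 genes and array weights 935. The count was 16 without 1 of the blastic samples, 19 and 20 without either of 2 of the myeloid samples, and 234 without the third.

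The changes of blastic and myeloid cells against the shared lymphoid samples overlapped in 765 genes called in the same direction (431 higher and 334 lower) and 2 in opposite directions. Independent lists of these sizes would share 69.7 higher and 38.2 lower genes. In 100 simulations all samples, lymphoid ones included, were replaced by independent noise without change, and the median of shared genes was 0. As limma called a median of 0 genes in each simulated comparison, that count cannot show what the shared lymphoid samples add. The simulations also leave out that some patients gave 2 fractions. With the lymphoid samples split so that each comparison had its own 3, the median of 20 splits was 371 shared genes (328 to 523). The smaller lymphoid groups also lowered the calls, to medians of 718.5 blastic and 1219 myeloid genes. Independent lists would then share medians of 22 higher and 14.9 lower genes. The drop from 765 therefore mixes the loss of shared samples with the loss of calls. Across genes, which are not independent replicates, the fold changes correlated at 0.732, against 0.335 in the simulations and 0.631 with split lymphoid samples. Their covariance was 1.14 against 0.091 in the simulations, a difference of 1.04.

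The erythroid fraction came from 1 sample, so its values carry no replicate check and no test. Red cell genes were far above the 6 lymphoid samples of the patients: AHSP, the chaperone of alpha globin, lay at 13.53 against 5.78 ± 1.10 (n = 6), or at least 216-fold higher. ALAS2, the first enzyme of red cell heme synthesis, lay at 12.56 against 5.82 ± 0.65, or at least 107-fold higher. The carbonic anhydrase CA2 (151-fold), the membrane receptor CD36 (135-fold), the globin HBM (128-fold), LXN (185-fold), PRKAR2B (103-fold), the adhesion molecule EPCAM (94.3-fold), the eosinophil granule protein PRG2 (92.1-fold) and the reductase AKR1C1 (85.8-fold) made up the other largest differences. ETS1, a transcription factor of lymphocytes, lay at 2.91 against 12.77 ± 0.49, or at least 932-fold lower. PAG1 (317-fold), GZMB (277-fold), RORA (193-fold), GZMA (188-fold), FGFBP2 (178-fold), RASGRP1 (170-fold), TGFBR3 (159-fold), GZMH (149-fold) and IL7R (140-fold) were the other largest negative differences.

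All 10 heme biosynthesis genes and 17 of 18 erythroid lineage genes lay above every lymphoid sample, with median differences of 4.23 and 4.03, each above all of 10000 random lists of the same size and level (percentile 100). FECH, which inserts iron into heme, was 24.3-fold higher, UROD 22-fold, the membrane skeleton protein EPB42 61.9-fold and the delta globin HBD 85.2-fold, while HBB, already at 11.72 ± 1.15 in lymphoid samples, was 7.35-fold higher. Cell cycle genes (25 of 26 above, median 3.59) and oxidative phosphorylation genes (25 of 28 above, median 1.45) were also at percentile 100, with RRM2 60.3-fold and UQCRC1 9.77-fold higher. In the mast cell, basophil and eosinophil list 5 of 6 genes lay above (median 3.57, percentile 100), and in the HOX and MEIS list 5 of 6 (median 2.29, percentile 99.82), with MEIS1 12.7-fold higher. Of 10 MHC class II genes 8 lay below (median -2.74, percentile 0), with CD74 13.7-fold and HLA-DRA 10.3-fold lower, while RFX5 and RFXAP, regulators of that class, lay above. Of 23 interferon response genes 11 lay below and 3 above (median -1.54, percentile 0), and of 20 immediate early and stress genes 11 below and 1 above (median -1.80, percentile 0.01). All 26 T cell genes and 20 of 22 NK and cytotoxic genes lay below (medians -5.28 and -5.27), while the ribosomal protein list had a median of 0.01. Of the 11110 genes, 4228 lay outside the lymphoid range by at least 2-fold of the lymphoid mean, 2361 above and 1867 below. Each patient's lymphoid sample set against the other 5 gave 427 to 3954 such genes, against a range set by 1 sample fewer. The count alone therefore says little about erythroid cells.

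The lymphoid sample of the healthy donor was also a single sample without a test. Cytotoxic genes were lower in it than in the lymphoid cells of the patients: GZMB lay at 6.84 against 11.51 ± 1.10 (n = 6), or 25.4-fold lower, and CX3CR1, the fractalkine receptor of cytotoxic lymphocytes and monocytes, at 4.35 against 9.86 ± 2.93, or at least 45.8-fold lower. TGFBR3 (29.1-fold), SLC35A1 (27.2-fold) and PCMTD1 (21.5-fold) were also lower. The vasodilator peptide gene ADM (47-fold), CSTA (35.2-fold), FCN1 (32-fold) and S100A12 (24.6-fold) were higher.

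Of 22 NK and cytotoxic genes, 19 lay below all 6 patient samples (median -2.05, percentile 0), with GZMA 14-fold, PRF1 13.9-fold and GNLY 9.36-fold lower, and of 26 T cell genes 10 did (median -0.94, percentile 0). Of 13 monocyte genes 6 lay above and 1 below (median 2.34, percentile 100), with SERPINA1 21.5-fold higher. Of the mature neutrophil list 3 of 13 genes lay above and 2 below (median 0.67, percentile 99.91), of the MHC class II list 1 of 10 above (0.81, 99.94) and of the B cell list 0 of 17 (0.45, 99.38). The number of genes outside the patients' range by at least 2-fold was 1338, 545 above and 793 below. When each patient's lymphoid sample was set against the other 5 in the same way, the number ranged from 427 to 3954, but against a range set by 1 sample fewer.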

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

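The tests of the first 2 patterns below, the settings used for the third and a fixed patient block in 2 comparisons were chosen only after the data were seen, while the other splits were set before.

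In 1 of the 6 lymphoid samples of patients, genes of blastic cells and of primary granules lay far above the other 5. The gap to the nearest sample, as a share of the whole range, was 0.813 for the mean of the stem and progenitor list (6.75 against 5.07 to 5.39) and 0.79 for that of the primary granule list (8.84 against 4.51 to 5.42), over the critical value for 6 samples. Among named genes the share was 0.897 for MSRB3 (9.02 against 2.67 to 3.32), 0.88 for DNTT, 0.869 for TFPI, 0.811 for DLK1 (10.36 against 3.64 to 4.90), 0.758 for MGST1, 0.71 for ZBTB8A, 0.702 for PTX3, 0.698 for CYTL1, 0.673 for CPA3, 0.671 for C1QTNF4, 0.653 for AZU1 and 0.633 for KIT. Outside this sample, HK3 was high in another (0.633), and CD8A (0.645) and the median of the deposited log2 values (0.855; 3.67 against 4.89 to 5.09) were low in a different one. Chance gives such a gap in about 1 in 20 groups, and of those tested 2 of 28 lists, 14 of 52 named genes and 1 of 3 array measures had one, 14 of the 17 in the same sample.

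The blastic cells of the same patient were also measured, and of 135 genes high in them 95.6% lay above the other 5 samples in this lymphoid sample. Each of the other lymphoid samples gave 0% to 8.2%, but of genes chosen anew, with this sample among those to be exceeded. Those shares were thus kept low in advance and cannot serve as a contrast. For genes high in the other blastic samples, this sample gave 51.4% to 58.3%. A carry-over of the patient's own blastic cells, at a median share of 9.56% (quartiles 7.06% to 13.2%), is therefore a candidate explanation, although the lymphoid gate should remove such cells. In the second patient with both fractions 17% of 112 such genes lay above the others, at a share of 0.1%. The flagged lymphoid sample was again among those to be exceeded, which limits this count in the same way. An exchange of the 2 samples is argued against, since 0 of the 2 had a T cell list mean nearer to the other group (lymphoid samples 9.19 to 10.13, blastic samples 4.99 to 5.21). That the lymphoid cells themselves express these genes was not tested and stays open.

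The mean of CXCL8, PTX3, CXCL2, EREG and IL1B, chosen after their values were seen, was 9.78 ± 1.67 in the 7 lesional samples, the lowest at 6.72, and 4.98 ± 0.73 in the 6 lymphoid samples, the highest at 6.02, and all 5 genes passed limma, while the healthy lymphoid sample lay at 7.53. Monocytes or neutrophils carried over into the blastic and erythroid samples, which sorting should remove, stay open, since only 2 of these 4 samples had each of the 5 genes above every lymphoid sample but monocyte and neutrophil list means below the highest lymphoid sample (3 by the mean of the 5). Each of the 5 lay above every lymphoid sample in the 6 blastic and myeloid samples, but only CXCL8, PTX3 and CXCL2 in the erythroid sample. Within the myeloid fraction they stay open too, since its gate can hold them and all 3 samples had the monocyte list above every lymphoid sample. A response to handling also stays open, since the immediate early and stress list had a median of -0.12 with members from -2.18 to 2.89, as does an untested difference between the lineages.

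Interferon response genes were lower in myeloid cells, with list means of 5.73 to 6.21 against 6.53 to 8.35 in the patients' lymphoid samples, 6.56 to 7.47 in blastic, 6.51 in the erythroid and 7.65 in the healthy lymphoid sample. The median log2 change of -1.61 was -1.42 with the GAPDH difference between 3' and 5' probe sets as a covariate (camera adjusted p = 1.42e-05), -1.14 without the 2 lymphoid samples that carry myeloid transcripts (0.00015) and -1.87 on the values as deposited without the array normalized apart (5.08e-06). Each of these is thus argued against as the whole source, though the call is lost at adjusted p = 0.268 with an estimated correlation. A difference between the lineages may remain, and it was not tested apart from these.

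Blastic and myeloid cells differed in 59 genes by limma, the direct test of the difference between their changes. The medians of the lists that differed by camera were 3.42 (stem and progenitor), 2.19 (mast cell, basophil and eosinophil), 1.80 (MHC class II), 0.92 (interferon response) and 0.40 (recurrently mutated in MDS) above 0. They were -3.74 (secondary granule), -1.86 (primary granule), -1.83 (mature neutrophil), -1.30 (monocyte) and -0.62 (Toll-like receptor and inflammasome) below it. With an estimated correlation only the stem and progenitor list passed.

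Other splits of the same samples were counted for each comparison. For lesional against lymphoid cells, 1 of 100 splits, the real one with 2183 genes, gave as many, and the highest other gave 2. For blastic against lymphoid cells, 1 of 84, the real one with 1176, gave as many, the highest other giving 125, and for myeloid against lymphoid cells 1 of 84, the real one with 2013, the highest other giving 932. A grouping by chance is argued against for these 3, with a share of splits under 0.05. The other splits mix lymphoid and lesional cells within a group, which widens its spread and can lower their counts. Among splits that part as many same-patient pairs, 42 in the first and 19 in the second comparison, the highest other was 0 in each. For blastic against myeloid cells the real split gave 59 and the highest of the others 29, 1 of 10 splits giving as many, which is too few for a share under 0.05, and among the 5 that part as many pairs the highest was 15.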

How the results depend on the processing

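The settings without the array normalized apart, without the 2 lymphoid samples that carry myeloid transcripts, with the GAPDH covariate, with a fixed block for myeloid cells, and with arrays centred for lists were chosen only after the data were seen. No named gene or called list changed sign in the settings run for it, but the myeloid majority turned to 660 higher and 883 lower with arrays centred, and calls changed sign with the fixed block (66 myeloid, 8 lesional), the mean of probe sets (11 lesional, 7 myeloid, 2 blastic) and, 1 at most, elsewhere. Of 139 values of the 8 main results under other settings, 109 stayed within 1.5 times or on the same side of the test, 20 were weaker and 10 stronger. Of 1081 values of 47 called lists 62 were weaker, of 4490 values of 306 named genes 459 were weaker and 27 stronger, and of 240 values of 30 single-sample genes 11 moved. Of 47 list calls, 8 held with an estimated correlation. Testing probe sets singly gave 3527 lesional and 3131 myeloid calls, being counts of probe sets. On the values as deposited 1150 myeloid and 22 blastic against myeloid genes passed. Array weights gave 3525 lesional, 2262 blastic, 4742 myeloid and 935 blastic against myeloid genes. With the patient as a random block 1959 blastic and 141 blastic against myeloid genes passed. As a fixed block, which spends most degrees of freedom, 47 lesional, 0 blastic, 0 myeloid and 0 blastic against myeloid genes passed limma (1826, 1918, 1011 and 838 at an unadjusted p of 0.05). The lesional value then rests only on patients with both blastic and lymphoid cells. The SAM-type test gave 3365 lesional and 16 blastic against myeloid genes, against 1703 blastic and 2762 myeloid. A fit of blastic and myeloid samples alone gave 0 in limma (1312 unadjusted). Without the array normalized apart, as deposited, 38 blastic against myeloid genes passed. The GAPDH covariate left 1408 lesional and 1323 myeloid genes. Splitting the lymphoid samples gave 371 shared genes, but also lowered the calls of each comparison. Leaving out each sample gave 1744 to 2279 lesional, 588 to 1224 blastic, 1193 to 2415 myeloid and 16 to 234 blastic against myeloid genes, 46 to 54 list calls, and median differences of 7.19 to 7.41 for the erythroid and 4.71 to 4.97 for the healthy sample. Where no construction is named, the cause was not tested. Signal over background limits genes near log2 6, and probe sets of 1 gene may differ, as for GATA2 (-0.22 to 4.26).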

Other observations

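The tests below were fixed in advance, but which genes of the naming rule are shown was chosen only after the results were seen. All fold changes below are against lymphoid cells. Without blastic or myeloid cells of healthy donors, they cannot be assigned to MDS rather than to lineage.

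Single genes of DNA methylation and Polycomb silencing differed between lymphoid cells and blastic or myeloid cells. The list as a whole did not pass camera against lymphoid cells (camera adjusted p = 0.967 for blastic and 0.463 for myeloid cells). Of 18 genes measured, 3 rose and 1 fell in blastic cells, and 2 rose and 2 fell in myeloid cells. Among all genes tested, 10.6% passed limma in blastic and 18.1% in myeloid cells, so the counts do not set this list apart. UHRF1, which guides the copying of methylation marks, was 17.2-fold higher in blastic cells (limma adjusted p = 0.00481) and 7.49-fold higher in myeloid cells (limma adjusted p = 0.0218). The methyltransferase DNMT3B was 4.57-fold higher in blastic cells (limma adjusted p = 0.000696) and 2.22-fold higher in myeloid cells (limma adjusted p = 0.0204). CBX7, a Polycomb subunit, was 5.34-fold and 5.3-fold lower (limma adjusted p = 0.00145 and 0.000949). ASXL1, a chromatin regulator often mutated in MDS, was 9.01-fold lower in myeloid cells (limma adjusted p = 0.00345). That is the largest fall among its 6 probe sets, whose log2 changes ranged from -3.17 to -0.21. When each of 9 samples was left out in turn, the myeloid calls of UHRF1 and DNMT3B were each lost in 2 fits. None of these genes passed limma between blastic and myeloid cells.

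The list of tumor suppressors methylated in MDS did not pass either (camera adjusted p = 0.226 for blastic and 0.706 for myeloid cells). Among its genes, the adhesion protein gene CTNNA1 was 5.98-fold higher in blastic and 3.47-fold higher in myeloid cells (limma adjusted p = 0.00286 and 0.0149, lost in 0 and 2 of 9 leave-one-out fits). The kinase DAPK1 was 17.2-fold higher in blastic (limma adjusted p = 0.000688) and 5.59-fold higher in myeloid cells (limma adjusted p = 0.00971), and SOCS1, an inhibitor of cytokine signaling, was 5.4-fold and 4.15-fold lower (limma adjusted p = 0.0214 and 0.0325, lost in 2 and 5 of 9 leave-one-out fits). The cyclin kinase inhibitor gene CDKN2A was 2.16-fold higher in myeloid cells (limma adjusted p = 0.0297, lost in 4 of 9). Nor did the immediate early and stress list pass (camera adjusted p = 0.929 and 0.701). In myeloid cells ATF3, a stress response factor, was 4.01-fold higher (limma adjusted p = 0.0443, lost in 7 of 9), the transcription factor KLF4 was 13.8-fold higher (limma adjusted p = 0.00151) and IER3, an early response gene, 13.6-fold higher (limma adjusted p = 0.000608), while the phosphatase DUSP2 was 7.65-fold lower (limma adjusted p = 0.0204, lost in 1 of 9).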
